A study of Mus musculus with 4 samples.

How the data were processed

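CD8+ T cells (DAPI-negative, CD45+, CD3+) were sorted from collagenase-digested livers with MC38 metastases, and bulk TCR libraries were made from their total RNA by reverse transcription, per the labels' protocols. There were 2 wild-type and 2 Vsig4-deficient samples, and 1 table of TRB clonotypes per sample. Genotypes and replicate numbers were taken from the sample labels. The submitters' processing notes name the genome build mm10. The program that assembled clonotypes, its version and its filters are not given in the sources used here.

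The deposited tables list, per the file headers, a clone count for each CDR3 nucleotide sequence with its V, D and J segments. These deposited counts were whole numbers with no normalization, and whether they are reads or molecules is not given in the sources used here. The deposited clone fraction equalled the count over the sum of counts in each table, and was used for this check alone. The deposited quality score, the lowest base quality in the CDR3, ran from 25 to 37. It was below 37 in 2.11% and 2.09% of wild-type and 2.68% and 3.34% of Vsig4-deficient clonotypes, and no filter was set on it.

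All listed rearrangements (52577, 81858, 52227 and 75300 in wild-type 1 and 2 and Vsig4-deficient 1 and 2) were TRB. Clonality of TRA, usage of TRAV and TRAJ segments, the TRAV11-TRAJ18 share of natural killer T cells, and the markers chosen for mucosal-associated invariant T cells, γδ T cells and B cells were planned and are not analysed here. Rearrangements out of frame or with a stop codon held 4.49%, 4.89%, 4.20% and 3.27% of counts and were left out of the main comparisons. A clonotype was an in-frame CDR3 nucleotide sequence with its V and J segment, with the first V segment taken where hits were tied (0.172% to 0.389% of clonotypes). All 38 V and J segments matched a mouse gene symbol in the RefSeq annotation of GRCm38.p6, the assembly family of mm10, from which positions were taken.

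Totals ranged from 901567 to 1269480 counts per library. Clonotypes with 1 count made up 21.4% and 17.6% of wild-type and 20.9% and 33.0% of Vsig4-deficient clonotypes, and the median clonotype had 7, 6, 5 and 3 counts. Richness, clonality (1 minus Shannon entropy over the logarithm of richness) and the effective number of clonotypes were means of 10 draws without replacement to 857452 in-frame counts, the smallest library. Shares of large clonotypes used all in-frame counts. Intervals on shares of single libraries were 95% Wilson intervals.

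Values of 2 against 2 libraries were compared with two-sided exact permutation tests of the difference in means over 6 splits. Overlap was compared over the 3 ways to pair 4 libraries. Segment usage and the abundance of amino acid clonotypes found in at least 3 libraries were tested with edgeR 4.0.16 (quasi-likelihood fits, offsets from library totals, segments with at least 10 counts over the libraries, Benjamini-Hochberg adjustment within each family, threshold 0.05) in R 4.3.3. DESeq2 1.42.0 with its size factors was an alternative. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. No other normalization was applied.

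These definitions and tests, the alternatives and the rule for named items were chosen before the data were examined. The rule named every segment past the threshold, the 5 most used per family, the members of fixed lists (Vβ8: TRBV13-1, TRBV13-2 and TRBV13-3; Vβ5: TRBV12-1 and TRBV12-2; segments used by natural killer T cells: TRBV13-2, TRBV29 and TRBV1; both J clusters), the 5 largest clonotypes of each library and the 5 most abundant shared clonotypes where none passed. An item that this rule names is not reported here. The alternatives were no draw to equal depth, TMM normalization, DESeq2, no filter on segments, clonotypes with 1 count left out, CDR3 amino acids alone as the clonotype, joining of sequences that differ by 1 nucleotide at a count ratio of 20, weighting by counts, the replicate number as a block, clonotypes under 1% of their share elsewhere left out, other definitions of the overlap and of the largest clonotypes, and each library left out in turn. The effective number of clonotypes, the number that makes up 50% of counts, the size classes and the tracing of the 50 largest clonotypes were not among these choices. A 5% version of the rule on shares elsewhere and a crossed replicate block were added after the data were seen.

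The repertoire functions were tested on made data with known answers, and 7 of 7 checks came within 2% of the true value. The edgeR step was tested on counts simulated from the real totals and spread. It recovered 28% of 1.5-fold and 83% of 2-fold changes of TRBV segments by clonotypes (23 segments), 4% and 12% by counts (24 segments), and 100% and 100% for TRBJ segments (12 segments). For shared clonotypes (6359 tested) it recovered 0% of 4-fold and 0% of 16-fold changes. The biological coefficient of variation was 13.8%, 34.7%, 2.86% and 143% in the same order. The 5% rule was tested on a simulated 2% carry-over of one library into another and removed 31.3% of the carried-over clonotypes with 63.8% of their counts. Clonotypes found in both libraries had been taken out of the recipient beforehand, so removal of truly shared clonotypes was not tested.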

Results

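T-cell receptor β (TRB) repertoires were measured in CD8+ T cells sorted from livers that carried metastases of MC38, a mouse colon adenocarcinoma line (the sample labels call these tumours melanomas). Wild-type mice were compared with mice lacking Vsig4, which encodes a complement receptor of the immunoglobulin superfamily found on Kupffer cells, the resident macrophages of the liver. Cells were collected on day 14 after injection of the tumour cells. There were 2 libraries per genotype, named here wild-type 1 and 2 and Vsig4-deficient 1 and 2. The labels do not say whether the libraries of a genotype came from separate animals, so p-values measure only the spread between these samples. The Morisita-Horn index of overlap (0 for disjoint, 1 for identical repertoires) was 0.0396 between the wild-type and 0.0118 between the Vsig4-deficient libraries. That argues against repeat libraries of the same cells, but part of the spread may still be technical. Vsig4 transcripts were not part of the assay, and the genotype is therefore taken from the labels.

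The libraries held 916335 and 901567 counts in wild-type mice and 1000179 and 1269480 counts in Vsig4-deficient mice. In-frame TRB rearrangements took 875201, 857452, 958198 and 1227914 of these counts. They formed 47558 and 73769 distinct clonotypes in the wild-type libraries and 47017 and 70126 in the Vsig4-deficient libraries, where a clonotype is a CDR3 nucleotide sequence with its V and J segment. CDR3 is the loop that spans the V(D)J junction and carries most contacts of the receptor with peptide. The TRB locus lies on chromosome 6, and the listed segments ran from Trbv1 (start 40891296) to Trbv31 (end 41558371) in mm10 coordinates.

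The first comparison asked whether loss of Vsig4 in the host went with a different degree of clonal expansion among liver CD8+ T cells. Expansion was read from TRB counts of RNA libraries, which do not give clone sizes in cells. In Vsig4-deficient mice the 10 largest clonotypes held 24.8% and 28.8% of in-frame TRB counts, against 8.93% and 5.13% in wild-type mice. The means were 26.8% ± 2.77 (SD, n = 2) and 7.03% ± 2.69 (SD, n = 2), a 3.81-fold ratio. Clonality, which is 0 for an even repertoire and 1 for a monoclonal one, was 0.283 ± 0.0248 (SD, n = 2) in Vsig4-deficient and 0.101 ± 0.0275 (SD, n = 2) in wild-type libraries. Half-abundance was reached with far fewer clonotypes in the absence of Vsig4: 50% of counts came from the 310 and 454 largest clonotypes, against 3993 and 8933 in wild-type mice. The effective number of clonotypes, the exponential of the Shannon entropy, was 2447 ± 288 (SD, n = 2) in Vsig4-deficient and 21173 ± 11699 (SD, n = 2) in wild-type libraries, an 8.65-fold ratio that was 5.27-fold without wild-type library 2.

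**Figure D1:**
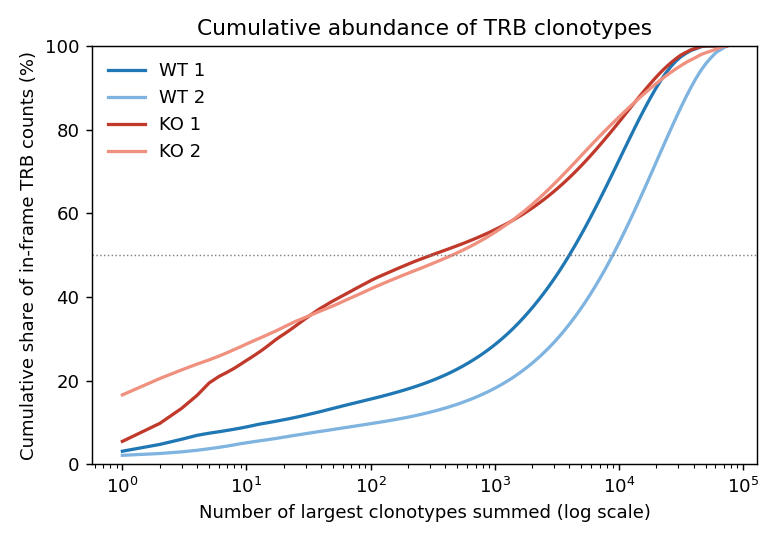
Cumulative share of in-frame TRB counts (y axis, percent) against the number of largest clonotypes summed (x axis, log scale), 1 line per library, WT for wild-type and KO for Vsig4-deficient, with a dotted line at 50%. The Vsig4-deficient libraries reached 50% with 310 and 454 clonotypes and the wild-type libraries with 3993 and 8933.

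Both Vsig4-deficient libraries lay above both wild-type libraries in clonality, with 0.266 and 0.301 against 0.121 and 0.0819. The difference of 0.182 in the means exceeded the SD within either genotype. The two-sided exact permutation test gave p = 0.333 for clonality and p = 0.333 for the share of the 10 largest clonotypes, and 0.333 is the smallest p that 6 splits of 4 libraries allow, so the design cannot pass a threshold of 0.05.

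Large clonotypes were more numerous in the Vsig4-deficient libraries. Clonotypes above 0.1% of counts numbered 71 and 60 in Vsig4-deficient and 30 and 21 in wild-type libraries, and held 41.5% and 38.9% of counts against 11.8% and 6.59%. Clonotypes above 1% numbered 7 and 4 in Vsig4-deficient and 3 and 1 in wild-type libraries, with 22.0% and 24.0% of counts against 5.97% and 2.14%. The class between 0.001% and 0.01%, which held most wild-type counts (61.9% and 69.3%), held 36.8% and 32.4% of counts in the Vsig4-deficient libraries. The exact permutation p was 0.333 for each of these shares.

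**Figure D2:**
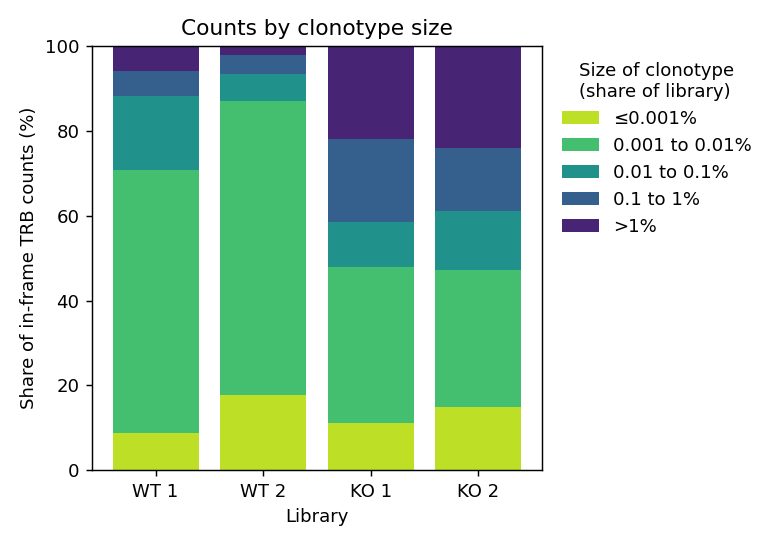
Share of in-frame TRB counts (y axis, percent) held by clonotypes of 5 size classes, stacked for each of the 4 libraries, WT for wild-type and KO for Vsig4-deficient. Clonotypes above 1% held 5.97% and 2.14% of counts in the wild-type and 22.0% and 24.0% in the Vsig4-deficient libraries.

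The largest clonotypes of both wild-type libraries and of Vsig4-deficient library 1 were distinct. In Vsig4-deficient library 1 the largest was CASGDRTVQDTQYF with TRBV13-2 and TRBJ2-5 (CDR3 nucleotides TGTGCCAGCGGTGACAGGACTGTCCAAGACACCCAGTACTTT), at 52404 counts, or 5.47% (95% Wilson interval 5.42 to 5.51). The largest of wild-type library 1 was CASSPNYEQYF with TRBV13-3 and TRBJ2-7 (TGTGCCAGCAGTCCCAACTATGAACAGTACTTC), at 27298 counts, or 3.12% (95% Wilson interval 3.08 to 3.16). That of wild-type library 2 was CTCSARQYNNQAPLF with TRBV1 and TRBJ1-5 (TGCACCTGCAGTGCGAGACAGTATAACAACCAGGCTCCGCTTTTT), at 18318 counts, or 2.14% (95% Wilson interval 2.11 to 2.17). These intervals cover counting error only, since amplified copies of a transcript are not independent molecules.

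Other large clonotypes held 2.95% to 4.29% of counts each in Vsig4-deficient library 1, 0.9998% to 3.90% in Vsig4-deficient library 2, 0.504% to 1.62% in wild-type library 1 and 0.372% to 0.431% in wild-type library 2. In Vsig4-deficient library 1 they were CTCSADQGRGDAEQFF (TRBV1, 4.29%), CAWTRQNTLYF (TRBV31, 3.60%), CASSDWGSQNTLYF (TRBV13-3, 3.12%) and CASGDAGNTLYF (TRBV13-2, 2.95%). In Vsig4-deficient library 2 they were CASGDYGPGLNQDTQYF (TRBV13-2, 3.90%), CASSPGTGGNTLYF (TRBV12-2, 2.07%), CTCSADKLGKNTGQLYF (TRBV1, 1.39%) and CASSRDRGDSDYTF (TRBV3, 0.9998%). In wild-type library 1 they were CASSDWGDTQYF (TRBV13-3, 1.62%), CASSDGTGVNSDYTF (TRBV13-1, 1.23%), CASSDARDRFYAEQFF (TRBV13-1, 0.946%) and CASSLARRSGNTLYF (TRBV3, 0.504%). In wild-type library 2 they were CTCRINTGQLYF (TRBV1, 0.431%), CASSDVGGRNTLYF (TRBV13-1, 0.400%), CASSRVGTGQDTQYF (TRBV17, 0.375%) and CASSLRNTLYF (TRBV12-1, 0.372%).

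The number of distinct clonotypes did not separate the genotypes. After drawing each library to 857452 in-frame counts, richness was 47350 and 73769 in wild-type and 45918 and 61917 in Vsig4-deficient libraries. The means of 60560 ± 18681 (SD, n = 2) and 53917 ± 11313 (SD, n = 2) differed by less than the SD within a genotype (two-sided exact permutation p = 0.667). Without wild-type library 2 the difference turned from -6642 (Vsig4-deficient minus wild-type) to 6567 clonotypes, and without Vsig4-deficient library 1 it turned to 1357.

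The second comparison asked whether the genotypes differed in the V segments that CD8+ T cells used. With each clonotype counted once, TRBV13-2 was used most (12.6% ± 0.234 in wild-type and 13.2% ± 1.51 in Vsig4-deficient libraries, SD, n = 2 each). TRBV13-3 (9.15% and 9.78%), TRBV13-1 (9.06% and 9.68%), TRBV3 (8.98% and 9.30%) and TRBV12-1 (8.98% and 8.90%) followed. The TRBV13 segments, which encode the Vβ8 chains (Trbv13-2 at 41121396 to 41121832 of chromosome 6), took 30.8% and 30.8% of clonotypes in wild-type and 30.002% and 35.4% in Vsig4-deficient libraries. All 3 Vβ8 members had a higher mean in Vsig4-deficient libraries, with log2 ratios between 0.07 and 0.10, and 0 of 3 passed the test, also when adjusted over the list alone. The higher means came from Vsig4-deficient library 2 alone. Vsig4-deficient library 1 lay below both wild-type libraries for each member (TRBV13-2 at 12.2% against 12.7% and 12.4%).

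The Vβ5 segments TRBV12-1 and TRBV12-2 took 16.7% and 16.5% of clonotypes in wild-type and 18.2% and 16.1% in Vsig4-deficient libraries. TRBV12-2 had a log2 ratio of 0.12 and TRBV12-1 of -0.01, and 0 of 2 members passed the test or did so when adjusted over the list alone. The β segments that semi-invariant natural killer T cells use, TRBV13-2, TRBV29 and TRBV1, took 26.3% and 26.4% of clonotypes in wild-type and 25.8% and 28.3% in Vsig4-deficient libraries. TRBV1 had a log2 ratio of 0.17 and TRBV29 of -0.18, and 0 of 3 members passed, also when adjusted over the list alone. These segments are used by conventional CD8+ T cells as well, and the reference annotation lists Trbv29 as a pseudogene although in-frame clonotypes used it at 7.09% ± 0.271 (SD, n = 2) in wild-type libraries.

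edgeR's quasi-likelihood test called 0 of 23 TRBV segments between genotypes when clonotypes were counted once (smallest Benjamini-Hochberg adjusted p = 0.551), with 0 segments at an unadjusted p under 0.05 and 0 calls by DESeq2. Without Vsig4-deficient library 1 the count was 13 (5 higher and 8 lower), and without Vsig4-deficient library 2 it was 1. In these fits the lone Vsig4-deficient library is assumed to vary like the wild-type pair.

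Weighted by counts, V segment shares include the size of each clonotype. TRBV3 held 8.03% ± 0.990 of counts in Vsig4-deficient and 13.0% ± 0.484 in wild-type libraries (SD, n = 2 each), with a log2 ratio of -0.70 ± 0.25 (SE). DESeq2 with its size factors gave TRBV3 a smaller log2 ratio of -0.40 (adjusted p = 0.416). Each SE here was derived from the log2 ratio and the F statistic of edgeR's quasi-likelihood test. TRBV14 held 2.58% ± 0.719 and 1.38% ± 0.144 (SD, n = 2 each), with a log2 ratio of 0.90 ± 0.37 (SE). TRBV13-2 held 21.5% ± 1.77 and 20.6% ± 1.502, TRBV13-1 10.2% ± 0.170 and 13.6% ± 1.295, and TRBV1 12.2% ± 0.585 and 9.55% ± 1.65 of counts in Vsig4-deficient and wild-type libraries (SD, n = 2 each). TRBV3 and TRBV14 were singled out here after their values were seen.

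The fixed groups gave no call by this measure. The Vβ8 segments together held 48.7% and 57.8% of counts in Vsig4-deficient and 53.7% and 46.7% in wild-type libraries, the Vβ5 segments 8.62% and 9.18% against 8.28% and 9.24%, and the segments used by natural killer T cells 38.4% and 34.1% against 34.1% and 34.5%. In each of these groups 0 members passed, also when adjusted over the list alone. Among 24 TRBV segments edgeR's quasi-likelihood test called 0 (smallest adjusted p = 0.180) with 4 at an unadjusted p under 0.05, and DESeq2 called 1, TRBV14 (log2 ratio 1.2004, adjusted p = 0.000888). Single clonotypes made up part of the TRBV14 counts: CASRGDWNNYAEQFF held 0.967% of all counts in Vsig4-deficient library 1, where TRBV14 held 3.08%, and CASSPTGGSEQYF 0.771% in library 2, where it held 2.07%. With clonotypes counted once, TRBV14 was at 3.64% in Vsig4-deficient and 3.87% in wild-type libraries. Without Vsig4-deficient library 1 edgeR called 5 segments and without Vsig4-deficient library 2 it called 2. On simulated data of this comparison the test recovered 12% of 2-fold changes, against 83% for clonotypes counted once.

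**Figure D3:**
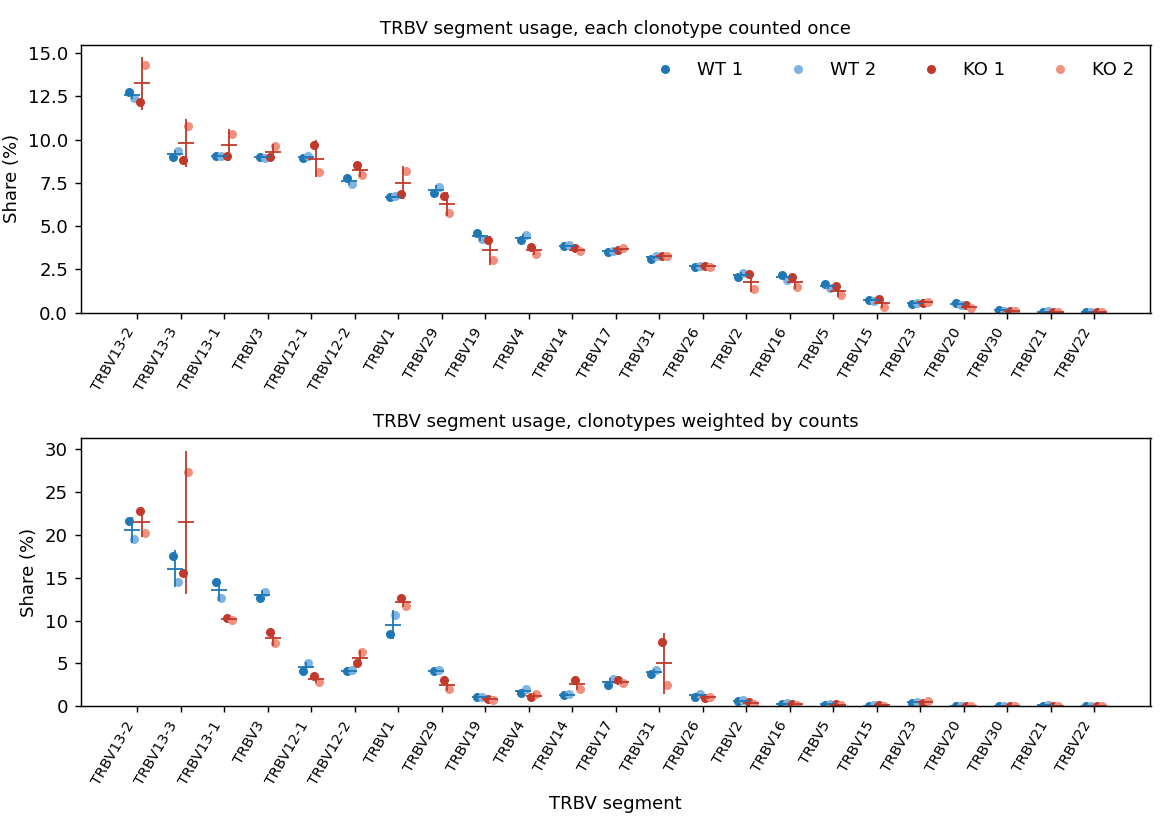
Share of in-frame TRB clonotypes (upper panel, percent) and of in-frame TRB counts (lower panel, percent) per TRBV segment, with points for the 4 libraries, WT for wild-type and KO for Vsig4-deficient, and dashes with bars for the mean ± SD of each genotype (n = 2). TRBV3 held 12.7% and 13.4% of counts in the wild-type and 8.73% and 7.33% in the Vsig4-deficient libraries, and no segment passed edgeR's test.

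With each clonotype counted once, J segment usage was close to equal in the genotypes. TRBJ2-7 was used by 19.8% ± 0.111 of clonotypes in wild-type and 18.9% ± 0.634 in Vsig4-deficient libraries (SD, n = 2 each), followed by TRBJ2-1 (14.1% and 14.5%), TRBJ2-5 (12.1% and 12.1%), TRBJ1-1 (9.52% and 9.60%) and TRBJ2-4 (8.67% and 8.73%). Segments of the second J cluster, which lies 3′ of the first (Trbj2-1 starts at 41542754 and Trbj1-1 at 41533864 of chromosome 6), took 69.4% and 68.7% of clonotypes in wild-type and 67.7% and 68.4% in Vsig4-deficient libraries. Weighted by counts, the first cluster held 25.9% and 27.7% in wild-type and 23.6% and 23.1% in Vsig4-deficient libraries. The two-sided exact permutation test gave p = 0.333 for this share, the smallest that 4 libraries allow. Single J segments were tested by clonotypes alone. By clonotypes, 5 of 6 members of the first cluster had a higher mean in Vsig4-deficient libraries, among them TRBJ1-2 (log2 ratio 0.11), TRBJ1-6 (0.13) and TRBJ1-5 (0.14). TRBJ1-4 (0.01) was also above 0 and TRBJ1-3 had a log2 ratio of -0.05. In the second cluster 3 of 6 were higher and 3 lower, with TRBJ2-3 at -0.10 and TRBJ2-2 at 0.03.

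None of these passed the test. edgeR's quasi-likelihood test called 0 of 12 TRBJ segments (smallest adjusted p = 0.0969) with 2 at an unadjusted p under 0.05, TRBJ1-2 and TRBJ2-3, and DESeq2 called 0. Adjusted over the list alone, 0 members of either cluster passed (smallest adjusted p = 0.0699 by edgeR, in the first cluster). The count was 6 without Vsig4-deficient library 1 and 1 without Vsig4-deficient library 2.

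CDR3 properties were compared because the amino acids of the loop shape recognition of self and foreign peptides, and CD5, named with VSIG4 in the title of the series, is a receptor whose level on T cells follows their reactivity to self. Mean CDR3 length was 13.93 ± 0.0137 amino acids in wild-type and 13.95 ± 0.0105 in Vsig4-deficient clonotypes (SD, n = 2 each), a difference of 0.0135 (two-sided exact permutation p = 0.667). Hydrophobic residues at both CDR3 positions 6 and 7, a property linked to self-reactivity, were present in 3.31% ± 0.117 of wild-type and 3.31% ± 0.1204 of Vsig4-deficient clonotypes (SD, n = 2 each; two-sided exact permutation p = 0.667). Weighted by counts, the shares were 3.78% and 3.85% in wild-type and 2.43% and 2.58% in Vsig4-deficient libraries, a difference of -1.32 percentage points (two-sided exact permutation p = 0.333).

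The last comparison asked whether libraries of a genotype shared receptors. Most clonotypes were private: of CDR3 amino acid sequences with their V and J segments, 157932 occurred in 1 library, 22011 in 2, 4795 in 3 and 1564 in all 4. The Morisita-Horn index, which is 0 for disjoint and 1 for identical repertoires, was 0.0396 between the wild-type libraries, 0.0118 between the Vsig4-deficient libraries and 0.000656 to 0.00351 between genotypes. The wild-type libraries shared 9000 amino acid clonotypes and the Vsig4-deficient libraries 9878, against 4448 to 9375 for pairs of different genotypes. The mean index within genotypes exceeded that between genotypes by 0.0234 (exact permutation p = 0.333 over the 3 ways to pair 4 libraries, the smallest possible).

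Many large clonotypes were also listed at low level in the other library of the genotype, to an extent that differed between directions. All 50 of the 50 largest clonotypes of Vsig4-deficient library 1 were listed in Vsig4-deficient library 2, at a median of 1.62% of their share, and 49 of the 50 largest of wild-type library 2 were listed in wild-type library 1, at a median of 0.905%. In the opposite directions 33 of 50 were listed in Vsig4-deficient library 1, at a median of 0.0948%, and 40 of 50 in wild-type library 2, at a median of 0.434%. Between genotypes the highest median was 0.187% (42 of the 50 largest of wild-type library 2 listed in Vsig4-deficient library 2), above the lowest value within a genotype. When clonotypes under 5% of their share elsewhere were left out, a setting chosen after this was seen, the excess of the index within genotypes was 0.00451.

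**Figure D4:**
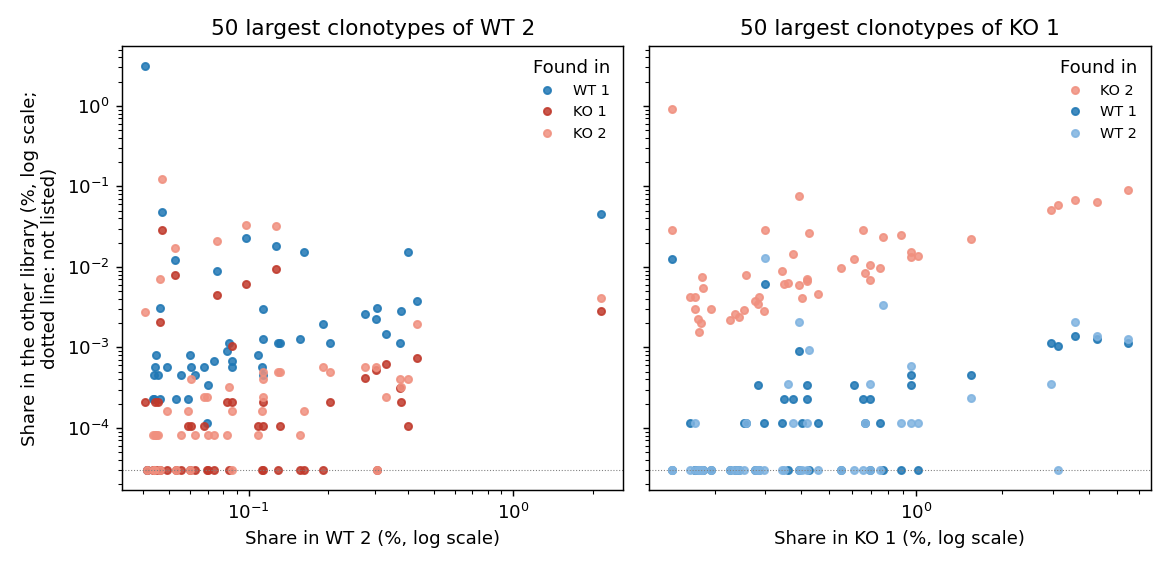
Share of the 50 largest clonotypes of wild-type library 2 (left) and Vsig4-deficient library 1 (right) in their own library (x axis, percent, log scale) and in each other library (y axis, percent, log scale), 1 point per clonotype and library, with WT for wild-type, KO for Vsig4-deficient and points on the dotted line for clonotypes not listed. In the right panel all 50 clonotypes were found in Vsig4-deficient library 2, at a median of 1.62% of their share.

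Abundance was compared for the 6359 amino acid clonotypes found in at least 3 libraries. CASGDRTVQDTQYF, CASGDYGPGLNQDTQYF, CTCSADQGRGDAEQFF and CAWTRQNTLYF were among the 5 most abundant, and each was large in a single Vsig4-deficient library. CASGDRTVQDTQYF had 52404 counts in Vsig4-deficient library 1, 1110 in Vsig4-deficient library 2, and 10 and 13 in the wild-type libraries. A few counts were enough to be listed: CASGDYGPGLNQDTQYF had 47928 counts in Vsig4-deficient library 2, 70 in Vsig4-deficient library 1, and 2 and 1 in the wild-type libraries. Without clonotypes under 5% of their share elsewhere 5312 were tested. Of these edgeR called 0, with 44 at an unadjusted p under 0.05. edgeR's quasi-likelihood test called 0 of 6359 clonotypes (smallest adjusted p = 0.9997) with 170 at an unadjusted p under 0.05, whereas DESeq2 called 118 (79 higher and 39 lower in Vsig4-deficient libraries). On simulated data of this comparison edgeR's test recovered 0% of 16-fold changes, so single shared clonotypes could not be resolved with 2 libraries per genotype.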

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

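The tests of carry-over between libraries and of fewer cells were chosen after the clonality values had been seen, and those of the largest clonotype and of out-of-frame rearrangements before.

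Out-of-frame TRB rearrangements, which encode no receptor and ride along in cells whose other allele is in frame, were outside the comparisons above and exceeded the wild-type level in the Vsig4-deficient libraries by 2 of 3 measures. After removal of near copies of in-frame clonotypes, 4736 and 7656 were listed in wild-type and 4962 and 4899 in Vsig4-deficient libraries, with 40106, 42831, 41195 and 40664 counts. Their clonality at equal depth was 0.160 in Vsig4-deficient library 1 and 0.161 in Vsig4-deficient library 2, above 0.111 and 0.0773 in the wild-type libraries. Their 10 largest members held 20.3% of out-of-frame counts in Vsig4-deficient library 1 and 13.6% in Vsig4-deficient library 2, above 10.3% and 7.37% in the wild-type libraries. The exact permutation p was 0.333 for both measures, the smallest that 4 libraries allow, and for the share of the 10 largest the genotypes lay closer together (3.22 percentage points) than the Vsig4-deficient libraries did to each other (6.69). The largest out-of-frame rearrangement did not follow, with 5.22% and 2.71% in Vsig4-deficient and 5.12% and 3.83% in wild-type libraries.

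The higher clonality of the Vsig4-deficient libraries was weighed against technical explanations by the gap between the lowest Vsig4-deficient and the highest wild-type library. This gap was 0.145 as reported at equal depth. Without the largest clonotype of each library it was 0.108, above the larger gap within a genotype (0.0346), which argues against 1 giant clonotype as the whole cause. Without clonotypes under 5% of their share elsewhere it was 0.146, against 0.0378 within a genotype. That rule removed only 0.190% to 1.21% of counts per library, so it could hardly move the gap and does not decide on carry-over. Fewer cells in the Vsig4-deficient libraries would lower richness along with evenness, but the fall in richness was only 0.0538 of that in the effective number of clonotypes (0.17 against 3.11 on the log2 scale), and -0.0781 of it without wild-type library 2 to 0.133 without Vsig4-deficient library 2, with each library left out in turn. Out-of-frame rearrangements, amplified apart from the in-frame transcripts of the same cells, had a gap in clonality of 0.0487 against 0.0337 within a genotype. For the share of the 10 largest the gap was 3.22 percentage points against 6.69, and for the largest alone it was -2.41. These measures differ, so they do not decide on uneven amplification of particular in-frame molecules, and none of them bears against that of a whole library. Technical values also separated the genotypes. Total counts were 1000179 and 1269480 in Vsig4-deficient and 916335 and 901567 in wild-type libraries, and 2.68% and 3.34% against 2.11% and 2.09% of clonotypes had a base quality under 37. The libraries were made from total RNA, so a share of counts depends on receptor transcripts per cell as well as on cells. These cannot be told apart here. Stronger expansion of some CD8+ clones in Vsig4-deficient hosts may underlie the pattern, as a hypothesis from 2 libraries per genotype. More uneven amplification, of particular molecules or of whole Vsig4-deficient libraries, stays open beside it. Tumour load and differences between animals unrelated to genotype were left untested.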

How the results depend on the processing

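The 5% rule on shares elsewhere, the crossed replicate block and the effective number with libraries left out were chosen after the data were seen. Clonality kept its direction and size under all 9 alternatives run (differences of 0.162 to 0.201), and the direction alone was kept by the share of the 10 largest clonotypes (9 alternatives, 8.40 points for the largest clonotype alone to 30.3 for the 100 largest), CDR3 length (7, 0.00386 to 0.0475 amino acids against 0.0135) and overlap (5, 0.00451 under the 5% rule to 0.0277, against 0.0234); 4 libraries cannot pass a threshold for these. Richness kept its direction in 7 of 9 alternatives and ranged from -19852 to 6567 with 1 library left out. The hydrophobicity difference, 0.00265 points as reported, was -0.0481 without clonotypes of 1 count, -1.32 weighted by counts, -0.00863 as a mean Kyte-Doolittle value and -0.0825 to 0.0878 with 1 library left out; the cause was tested for the weighting by counts alone, under other observations. Calls with 1 library left out ranged from 0 to 13 for TRBV by clonotypes, 0 to 5 for TRBV by counts, 0 to 6 for TRBJ and 0 to 0 for shared clonotypes; the calls came without a Vsig4-deficient library, where the lone library left takes its spread from the wild-type pair. DESeq2 called 1 TRBV segment by counts and 118 shared clonotypes, and the cause was not tested. The other alternatives gave 0 calls. With the replicate number as a replicate block there were 0 calls in each of the 4 families, and same-numbered libraries deviated with correlations of 0.155, -0.273, -0.613 and 0.0115 (TRBV by clonotypes, TRBV by counts, TRBJ, shared clonotypes), and with 2 pairs and no label of a shared animal or day the libraries share only a number. The crossed pairing gave 0 calls for TRBV by counts and 0 for TRBJ. The TRA results were not run, as the tables used here list TRB. Depth limits the rarest clonotypes, since 17.6% to 33.0% had 1 count.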

Other observations

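The tests of carry-over within genotypes, of carry-over among near-identical sequences and of counts per Vβ8 clonotype were chosen after the values that prompted them had been seen, and the other tests here before.

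Near-identical CDR3 sequences recurred among the large clonotypes of different libraries. Among the 100 largest clonotypes per library, 15 pairs from different libraries had the same V segment and length and differed by 1 amino acid, against a mean of 4.87 in 1000 random sets of the same V segments drawn from smaller clonotypes (permutation p = 0.003996). The random sets were matched for the V segment, but not for the J segment or CDR3 length. Without clonotypes under 5% of their share elsewhere there were 14 pairs against 4.73 (permutation p = 0.003996). The excess thus did not rest on clonotypes that this rule removes. On simulated carry-over the rule removed 63.8% of the carried-over counts, so carry-over as a source is not excluded. Convergence of expanded clones on similar receptors may contribute, as a hypothesis, and both genotypes took part in these pairs. The most connected group, noticed in this list, used TRBV3, in most members with TRBJ1-3, and had CDR3 sequences such as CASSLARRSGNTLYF, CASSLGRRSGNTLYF, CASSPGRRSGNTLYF and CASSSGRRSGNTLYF. This group supplied many of the 14 pairs, which are not independent of each other. Whether an excess is left without this group was not tested, so a general convergence of expanded clones is not shown. With all in-frame clonotypes kept, its TRBJ1-3 members held 0.654% and 0.139% of counts in the wild-type and 0.514% and 0.0189% in the Vsig4-deficient libraries, encoded by 11, 8, 9 and 11 nucleotide sequences.

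Other features of large clonotypes were mixed. The D2-encoded motif Asp-Trp-Gly (DWG) stood out among the 8 largest clonotypes of Vsig4-deficient library 1, where 2 had it, but between ranks 9 and 100 it was more frequent than among smaller clonotypes in only 1 of the 4 libraries (wild-type library 2, 9.78% against 6.29%), so the hypothesis that the DWG motif is more frequent in expanded clonotypes was not borne out. The lower share of hydrophobic CDR3 positions in the Vsig4-deficient libraries, weighted by counts, shrank without the 100 largest clonotypes of each library to 0.0635 of its size (from -1.32 to -0.0836 percentage points). The 100 largest clonotypes of each library may thus set most of that difference.

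Rearrangements were shared more within than between genotypes. Selection of the same receptors in both libraries of a genotype, as the only source, is argued against by out-of-frame rearrangements, which no antigen can select. Their mean Jaccard index was 3.68 times as high within (3.22%) as between genotypes (0.874%). Whether selection adds to the sharing of in-frame receptors cannot be told from this, since another source may raise both kinds of sharing. Carry-over of material between libraries of a genotype is consistent with an even dilution of large clonotypes in 1 direction per genotype: the share in the partner over the share in the donor had an interquartile ratio of 2.31 from wild-type library 2 to 1 and 1.98 from Vsig4-deficient library 1 to 2. In the opposite directions dilution was not even, with a ratio of 11.03 from wild-type library 1 to 2 and a first quartile of 0 from Vsig4-deficient library 2 to 1. Between genotypes the ratio was 3.73 from wild-type library 2 to Vsig4-deficient library 2, with 42 of 50 listed. Of the 20 largest out-of-frame rearrangements, 10 were listed from wild-type library 2 to 1 (median 0.179% of their share) and 19 from Vsig4-deficient library 1 to 2 (median 1.09%). The step at which carry-over could happen (sorting, amplification or index reads) stays open. So does the overlap that is left, because on simulated carry-over the 5% rule removed 63.8% of the carried-over counts.

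Vβ8 segments were frequent among clonotypes above 0.1% of counts, at 66.7% and 33.3% of them in the wild-type and 46.5% and 46.7% in the Vsig4-deficient libraries, against 30.7%, 30.8%, 29.98% and 35.4% of other clonotypes. Fisher's exact test, adjusted over 12 comparisons, gave p = 0.000849 and 0.890 in the wild-type and p = 0.0239 and 0.236 in the Vsig4-deficient libraries, and treats clonotypes of a library as independent. Among clonotypes at or below 0.1%, the median count of Vβ8 clonotypes was 3.2, 3, 2.5 and 2 times that of others (wild-type 1 and 2, Vsig4-deficient 1 and 2). A higher yield of counts per clonotype from these segments, for example from primer efficiency, could therefore contribute to the pattern (lowest ratio 2), but whether it gives an excess of the observed size was not tested, and wild-type library 2 had a ratio of 3 with little excess. Larger clones of Vβ8 cells at every size stay open, since both would raise the median.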
